A study of Homo sapiens with 8 samples.

How the data were processed

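Polyadenylated RNA was measured in 2 human lung adenocarcinoma cell lines with activating EGFR mutations, HCC4006 and HCC827. Each line was present as a culture carried in DMSO, the solvent control, and as a culture made resistant to the EGFR inhibitor gefitinib at 3 µM. Each of the 4 groups had 2 libraries, 8 in all. Per the labels' protocols, RNA was purified with a miRNeasy kit and libraries were made with TruSeq RNA v2, a kit that does not mark strand. Nothing says that the 2 libraries of a group came from separate cultures, so every p-value measures only the spread between these samples, which may be technical.

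The authors deposited gene-level FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) in 2 tables, 1 per cell line, with 48405 rows each. The submitters' processing notes name TopHat 1.4.1, Cufflinks 1.3.0 and Cuffdiff, on genome build hg19. The gene annotation and the options used are not given in the sources used here. The column names carry the line, the treatment and a letter, A or B, while the labels number the replicates. The letters were not tied to the numbers and name only the columns of a group. There were 0 per-sample columns outside the 8 groups' libraries. Depth is unknown, because FPKM hold no counts and no read totals were used, so no counting interval or detection floor can be given. The 2 tables may have been normalized separately, so every change was taken within a line, and levels set across lines depend on each table's scale. The median row above 0 lay between 53.6 and 59.0 FPKM in the 8 libraries, which is high for FPKM and leaves a further scaling by the authors possible. Ratios within a table do not depend on such a factor, except through the pseudocount.

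Gene names were used as the tables give them. The rows carried 42971 distinct names on 31341 loci, 1795 rows joined the names of several genes with commas, 24678 rows shared a locus with another row, and 23 names had been turned into dates by a spreadsheet and were not used by name. Of the names, 21469 matched a reference table of gene symbols. Genes on joined or shared loci, overlapping genes and antisense pairs are uncertain because fragments cannot be told apart without strand. FGF2 is such a case, since it overlaps NUDT6 on the opposite strand. A member of a list was taken only from a row on the gene's own chromosome, which left out 2 members found on another chromosome only.

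The following was computed from the tables. Values were tested as log2(FPKM + 0.5) in limma 3.58.1 (R 4.3.3), with lmFit and eBayes with a mean-variance trend, over rows with a mean FPKM of at least 0.5 in the fit. Adjusted p-values are Benjamini-Hochberg values over all rows of the fit, and a gene was called at an adjusted p below 0.05. Fold changes are differences of log2(FPKM + 0.5), resistant minus DMSO, which understates the change of low genes. Each line was fitted alone with its 4 libraries. The difference between the lines was an interaction contrast over all 8 libraries, the change in HCC827 minus the change in HCC4006. Overlap of calls was tested with Fisher's exact test, which treats genes as independent, beside the overlap of independent lists. These fits, the named genes and the gene lists were fixed before the data were examined.

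The gene lists, 26 in all with 487 memberships of which 483 were found, covered epithelial junction genes, epithelial regulators and proteases, keratins, mesenchymal genes, transcription factors of the epithelial to mesenchymal transition (EMT), FGF ligands and receptors, EGFR family and ligands, other receptor tyrosine kinases and ligands, ERK output and feedback genes, the TGF-beta and BMP pathway, cell cycle genes, alveolar and airway lineage genes, neuroendocrine genes, stem cell associated genes, interferon-stimulated genes, MHC class I presentation, inflammatory cytokines and NF-kB targets, efflux, xenobiotic and NRF2 genes, BCL2 family and IAP genes, cholesterol synthesis, glycolysis, unfolded protein and heat shock genes, immune cell markers, endothelial markers, fibroblast markers and replication-dependent histone genes. A list with at least 5 measured members was tested with camera at a preset correlation of 0.01, which compares its genes with the other genes, with adjustment over the lists of a line. Beside it stand camera with an estimated correlation and fry. Fry asks whether a list's genes move on balance one way and does not compare them with other genes. With an estimated correlation, calls can be lost even where that correlation is near 0. In HCC4006 it was 0.000878 for junction genes and −0.00487 for regulators, below the preset 0.01. Their unadjusted camera p still rose from 1.71e-12 to 0.0162 and from 2.95e-14 to 0.0139. For cell cycle genes there the estimate was 0.947. A call lost with an estimated correlation thus need not come from correlated genes. A list's calls were also counted with p-values adjusted over the list alone.

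Genes were named by rule: FGF2, FGFR1, EGFR, ERBB2, ERBB3, MET, AXL, CDH1, VIM and ZEB1 in both lines, per line the 6 called genes with the largest rise and the 6 with the largest fall among those with a mean FPKM of at least 5 in the higher group and no overlap between groups, per list up to 2 called members in each direction, and the 5 genes most different between the lines in each direction. Because many of the largest changes stood against groups listed at 0, the second and the last part of the rule were applied again to genes above 0 in every library of the fit, a choice made after the zeros were seen. Genes outside the rule were chosen after their values were seen and are marked so where they appear.

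An exact 0 in these tables can be a failed estimate. A gene whose group is at 0 is described as listed at 0 with the values of its libraries and no fold change. Loci with at least 2 rows that reached 50 FPKM in any library were used to ask whether neighbours were at 0 together, over all pairs of such rows on a locus with the first at 0, so that loci with many rows weigh more. Rows at 0 in a group with a mean of at least 50 FPKM over the other groups were counted as well, and core ribosomal protein genes were listed, with 1000 FPKM as the level taken as high.

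The differences between the libraries of a group were compared per list with 10000 random lists of the same size matched on mean FPKM. Along chromosomes, medians of the change over runs of 15 neighbouring genes were compared with 1000 permutations of the gene order. These genes were protein coding, above 0 in the 4 libraries, with a mean FPKM of at least 20 and 1 row per locus. Genes within 2 Mb of EGFR and MET were compared with runs of as many such genes on all chromosomes. Those runs include the ones in the regions themselves. GC content and length came from the longest transcript of each gene in GENCODE 29, matched by name for 27447 rows (56.7%), and their trend was removed with cubic terms. Coordinates are those of the tables, on hg19. These steps and the figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

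The fit was tested on simulated data, in 10 draws with 200 changed genes each, for genes above 0 in the 4 libraries of a line. In HCC4006, with 16400 to 16414 genes tested, 49.7% of 4-fold and 95.1% of 16-fold changes were called and 8.06% of calls were false. In HCC827, with 15828 to 15858 genes tested, 53.8% and 97.4% were called and 9.76% of calls were false. The false share lay above the nominal 5% in both, and 0 changed genes were called with the wrong sign. The simulated fit held no rows at 0 and its genes varied independently. These shares therefore do not describe the fits over all rows, where many calls have a group at 0. The chromosome and list steps were tested on 8000 simulated genes, where 1 simulated region of 40 genes was found with 0 others and a list of 28 genes gave back a median of −1.46.

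The alternatives planned were pseudocounts of 0.1 and 1, no filter and a mean FPKM of at least 2, libraries rescaled by median ratio, quantile normalization, no mean-variance trend, a replicate block, single-line contrasts from a fit over all 8 libraries, calls of at least 2-fold, the other list tests and each library left out in turn. Added after seeing the data were a fit over genes above 0 in every library, a pseudocount of 10, a mean FPKM of at least 20, and genes above 0 with the replicate block. Reads were not used here, so exons, splice forms, variants and copy number were not analysed here.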

Results

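Gefitinib blocks the EGFR kinase, and lung cancer cells with activating EGFR mutations that are kept in the drug can grow out resistant. The study asked, per its title, whether resistance comes with cellular reprogramming and with an autocrine loop in which the growth factor FGF2 acts on its receptor FGFR1. Polyadenylated RNA of HCC4006 and HCC827 cells was given as FPKM with n = 2 libraries per group. Each line was present as a DMSO culture and as a culture resistant to 3 µM gefitinib. The labels name gefitinib for the resistant cultures alone. Effects of resistance and of the drug itself, where still present, cannot be told apart. Between 17406 and 19333 of 48405 rows lay above 0 in a library. The 10 highest rows held 15.6% of all FPKM in library A of the HCC4006 DMSO group and 5.3% to 10.3% in the other libraries. Depth is unknown.

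Many abundant genes that every growing cell uses were listed at 0 in whole groups. Of 73 core ribosomal protein genes, which build the ribosome, 10 were at 0 in both HCC4006 DMSO libraries and 4 in both resistant HCC4006 libraries. In HCC827 these were 5 in both DMSO libraries and 4 in both resistant libraries. In all, 10 were at 0 in some group while over 1000 FPKM in a library of another. RPL10, for example, was listed at 0 in both DMSO groups and at 4904 and 5972 FPKM in resistant HCC4006. KRT7, GUSB, SNRPD3 and RPL27A were listed at 0 in all 8 libraries. These 5 were chosen after their values were seen. Rows at 0 in both libraries of a group with a mean of at least 50 FPKM elsewhere numbered 684 in HCC4006 DMSO, 214 in resistant HCC4006, 724 in HCC827 DMSO and 252 in resistant HCC827. Among rows that reached 50 FPKM in some library, a row on the same locus as one at 0 was at 0 too in 96.3%, 81.5%, 93.5% and 84.2% of such pairs, against 7.76%, 3.16%, 8.42% and 3.74% of all these rows. A 0 is therefore given as listed at 0 and with no fold change, and fits over genes above 0 in every library stand beside the counts. The values given below for PDGFRA, OVOL2, MUC1, BUB1B and IFITM1 come from rows that also name FIP1L1, SNX5, KRTCAP2, PAK6 and IFITM2, so they cannot be assigned to 1 gene. Those of NDUFA13 and SNRPD3 also name YJEFN3 and GGT1. Rows of CLDN4, LSS, NKX2-1, PDGFRB, PSMB9, TPT1, RPLP2, RPL10 and RPL27A carry a second name too, in the last 4 that of a small nucleolar RNA.

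In resistant HCC4006, many epithelial genes fell. CDH1 and CDH3, which encode the adhesion molecules E-cadherin and P-cadherin, and the epithelial trafficking genes RAB25 and AP1M2 were among them. ZEB1 and ZEB2, which encode repressors of epithelial genes, rose, as did CDH2, the N-cadherin gene of mesenchymal cells. The chemokine gene CCL2 rose, while ERBB2 and ERBB3, which encode partners of EGFR, fell. Over genes above 0 alone, ZEB1, CDH2, ERBB2 and ERBB3 were not called. FGFR1, FGF2, VIM, MET and AXL were higher in both resistant libraries than in both DMSO libraries without passing the test, and EGFR did not pass it either.

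CDH1 (chromosome 16, 68771127 to 68869444) measured 1518 and 945 FPKM in the DMSO libraries and 3.03 and 3.29 in the resistant libraries, a log2 fold change of −8.36 (SE 0.32, adjusted p = 0.000781). ZEB1 (chromosome 10, 31596657 to 31818742) went from 3.93 and 7.44 to 56.3 and 58.3 FPKM, a log2 fold change of 3.29 (SE 0.38, adjusted p = 0.0189). ZEB2 (chromosome 2, 145145567 to 145278683) went from 1.58 and 1.36 to 79.4 and 78.0 FPKM, a log2 fold change of 5.33 (SE 0.24, adjusted p = 0.0012). ERBB3 (chromosome 12, 56473891 to 56497128) went from 215 and 110 FPKM to 6.90 and 13.6, a log2 fold change of −3.91 (SE 0.53, adjusted p = 0.0295). ERBB2 (chromosome 17, 37844392 to 37884915) went from 127 and 122 FPKM to 56.2 and 57.2, a log2 fold change of −1.13 (SE 0.19, adjusted p = 0.0497).

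Fitted over genes above 0 alone, the adjusted p was 0.0153 for CDH1, 0.0241 for ZEB2, 0.0686 for ZEB1, 0.0696 for ERBB3 and 0.146 for ERBB2. For FGFR1, VIM and FGF2, which the main fit did not call, it was 0.106, 0.116 and 0.14. Each library was also left out in turn, with the lone library of a group assumed to vary like the other group. Such a fit has fewer residual degrees of freedom, all from the other group. A call lost in it can come from lost power and need not rest on the library left out. CDH1 was then not called without resistant library A (adjusted p = 0.0816) or B (0.0805), nor ZEB1 without resistant A (0.336) or B (0.349). ERBB3 was not called without DMSO A (0.109), DMSO B (0.0739), resistant A (0.364) or resistant B (0.293). ERBB2 was not called without DMSO A (0.0667), resistant A (0.32) or resistant B (0.317). ZEB2 was called without each library in turn.

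The genes of the FGF loop that the study's title names did not pass the test in HCC4006. FGFR1 (chromosome 8, 38268655 to 38326352) measured 21.1 and 68.1 FPKM in the DMSO libraries and 345 and 428 in the resistant libraries, a log2 fold change of 3.32 (SE 0.64, adjusted p = 0.071). It passed in the fit over all 8 libraries (adjusted p = 0.0135) and with the replicate block by column letter, given below. Without DMSO library B its log2 fold change was 4.15. FGF2 (chromosome 4, 123747862 to 123844123) measured 92.4 and 103 FPKM in the DMSO libraries and 275 and 200.2 in the resistant libraries, a log2 fold change of 1.26 (SE 0.25, adjusted p = 0.0751). Its row overlaps NUDT6 on the opposite strand and carries a joined name, so its signal cannot be assigned to FGF2 alone. VIM, the vimentin gene of mesenchymal cells (chromosome 10, 17270257 to 17279592), measured 2036 and 3292 FPKM against 9074 and 9193, a log2 fold change of 1.82 (SE 0.31, adjusted p = 0.0513). It passed without DMSO library B (2.17, adjusted p = 0.0293), with a mean FPKM of at least 2 (0.0469), with quantile normalization (0.0328) and in the fit over all 8 libraries (0.0495). EGFR (chromosome 7, 55086713 to 55324313) had a log2 fold change of −0.15 (SE 0.31, adjusted p = 0.803). MET (chromosome 7, 116312247 to 116438440) had 0.21 (SE 0.19, adjusted p = 0.546). AXL, a kinase gene often tied to drug resistance (chromosome 19, 41725107 to 41767670), had 0.86 (SE 0.38, adjusted p = 0.302). The sign of the EGFR value turned without DMSO library A (0.20).

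**Figure D1:**
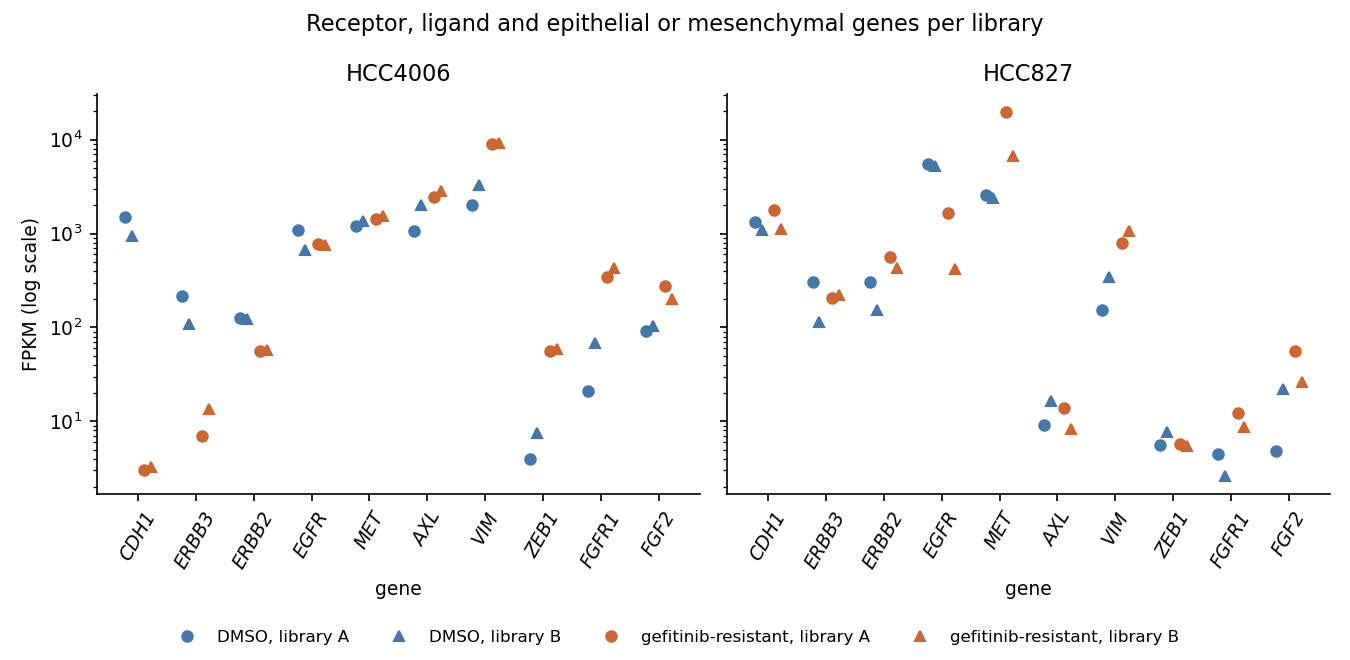
FPKM on a log axis of the 10 genes named in advance, 1 point per library, with HCC4006 left and HCC827 right. In HCC4006, CDH1 lay at 3.03 and 3.29 in the resistant libraries against 1518 and 945 in the DMSO libraries, while in HCC827 the 4 libraries lay between 1081 and 1804.

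In HCC4006, 1860 of 19881 genes were called, 1267 higher and 593 lower, all of them at least 2-fold. Of these, 1085 were listed at 0 in both DMSO libraries, 243 in both resistant libraries and 33 in 1 library. The other 499 lay above 0 in all 4 libraries, with 167 higher and 332 lower. Among the genes listed at 0 in DMSO were PFN1, which encodes an actin-binding protein of all cells (5632 and 6072 FPKM in the resistant libraries), TPT1 (6808 and 5647) and RPS4X (5671 and 5225). So were the row of KIF23 and RPLP1 (7007 and 6560), AP003035.1 (21528 and 23414) and AC006427.1 (6386 and 5358). At 0 in the resistant libraries were CD44 (8578 and 13596 FPKM in the DMSO libraries), MUC1 (2387 and 2250.3) and FKBP1A (1074 and 2204). So were TMSB4XP1 (2944 and 2208), NDUFA13 (2117 and 1548) and AC091047.2 (96613 and 41006). The count was 2031 without DMSO library A, 3565 without DMSO library B, 1411 without resistant library A and 1394 without resistant library B. The lower calls numbered 749, 1681, 89 and 83 in these, and the higher ones 1282, 1884, 1322 and 1311. Fitted over genes above 0 alone, 88 of 16484 were called, 17 higher and 71 lower. Of list members named below, OAS1, OAS2, NKX2-1, DDR1, SPRED3, BIRC3, BIK, CSF1R and PDGFRB were not called in that fit. Their adjusted p there lay between 0.0729 and 0.126.

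Among genes above 0, the largest rises were C1orf21, the peptidase gene MME, the cancer testis gene MAGEB2, ZEB2, the cytokine receptor gene IL7R and RP11-152P17.2, with log2 fold changes of 5.70, 5.60, 5.36, 5.33, 5.18 and 4.64. The largest falls were the secreted protein gene AGR2, TRIM29, SPOCK2, CDH1, RAB25 and AP1M2, with −9.31, −9.27, −9.27, −8.36, −8.04 and −7.56. MME went from 1.90 and 7.94 to 209.6 and 226 FPKM, and RAB25 from 1652 and 989.7 to 4.28 and 4.45. AGR2 spread widely, with 9534 and 1219 FPKM in the DMSO libraries and 10.7 and 2.10 in the resistant libraries. In the fit over genes above 0, MME (adjusted p = 0.0585), IL7R (0.0741) and AGR2 (0.0657) were not called and the others were, RP11-152P17.2 at 0.0491. Of the 28 genes named by rule that were called and above 0, 16 were called without DMSO library A, 18 without DMSO library B, 4 without resistant library A and 4 without resistant library B. C1orf21, ZEB2, TRIM29 and AP1M2 were called each time. A group listed at 0 has no spread between its libraries. A fit that takes its spread from such a group alone tends to keep the call. Leaving out libraries thus says little about the named genes with a group at 0.

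By list, epithelial junction genes were lower in resistant HCC4006 by camera (24 genes, median log2 fold change −3.01, adjusted p = 2.05e-11). The adjusted p = 0.195 with an estimated correlation. Of the members, 2 were called higher and 18 lower, and 2 and 20 when adjusted over the list alone. The 2 called higher were CLDN4 (222 and 284 FPKM in the resistant libraries) and CGN (139 and 177), both listed at 0 in DMSO. Besides CDH1, CDH3 fell from 1352 and 687 FPKM to 8.65 and 8.77 (log2 fold change −6.71, adjusted p = 0.00275), which leaving out resistant library A (0.177) or B (0.179) undid. Of members outside the naming rule, chosen after their values were seen, DSP, JUP, CLDN7, EPCAM and CRB3 had log2 fold changes of −5.55, −3.33, −4.60, −3.60 and −4.32. Epithelial regulators and proteases were lower as well (23 genes, median −3.28, adjusted p = 7.07e-13). Again adjusted p = 0.195 with an estimated correlation. Here 1 member was called higher and 17 lower, and 1 and 20 when adjusted over the list alone. The splicing regulator gene ESRP1 measured 1136 and 361 FPKM in the DMSO libraries and 1.45 and 0 in the resistant ones, and MUC1 was listed at 0 in the resistant libraries. OVOL2 was the member called higher, listed at 0 in DMSO with 676 and 604 FPKM in the resistant libraries. Keratins, the filament genes of epithelia, were lower in all 9 measured members (median −2.87, adjusted p = 0.000105), with an adjusted p = 0.403 with an estimated correlation. Of these, 5 were called lower, the same number when adjusted over the list alone. Only 4 members lay above 0 in all 4 libraries, too few to test the list over genes above 0. KRT17 measured 63.3 and 71.2 FPKM against 1.16 and 0, and KRT16 30.2 and 15.7 against 0.74 and 0.

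Mesenchymal genes were higher in HCC4006 (21 genes, median 1.39, adjusted p = 0.000501), with an adjusted p = 0.403 with an estimated correlation. Of these, 2 were called higher, and 6 when adjusted over the list alone. The fibronectin gene FN1 was listed at 0 in DMSO (63.7 and 99.9 FPKM in the resistant libraries), and CDH2 rose from 326 and 355 FPKM to 762 and 771 (log2 fold change 1.17, adjusted p = 0.0412). CDH2 was not called over genes above 0 alone (0.115), nor without resistant library A (0.301) or B (0.31). EMT transcription factors were higher (8 genes, median 1.06, adjusted p = 0.0136), with an adjusted p = 0.403 with an estimated correlation and 0.0537 without resistant library B. ZEB1 and ZEB2 were the 2 called of the list, and 3 were called when adjusted over the list alone. All 14 measured inflammatory cytokines and NF-kB targets had positive fold changes (median 2.20, adjusted p = 5.54e-05), with an adjusted p = 0.531 with an estimated correlation. Of these, 2 were called higher, and 10 when adjusted over the list alone. The 2 DMSO libraries stood apart for this list, with 9 of 11 members above 0 higher in A (median log2 A minus B 1.29). CCL2 rose from 227 and 233 FPKM to 2645 and 2783 (log2 fold change 3.56, adjusted p = 0.00156), a call that leaving out resistant library A (0.0584) or B (0.0611) undid. CCL20 was listed at 0 in DMSO (6.03 and 6.05 in the resistant libraries). The cytokine genes IL6 and IL8 were chosen after their values were seen. IL6 measured 55.0 and 12.3 FPKM in the DMSO libraries and 150.2 and 185 in the resistant libraries (adjusted p = 0.17), and IL8 37.7 and 3.22 against 179 and 198 (adjusted p = 0.178).

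Interferon-stimulated genes, which cells turn on against viruses, were lower in HCC4006 (21 genes, 18 with negative changes, median −0.53, adjusted p = 0.0104), with an adjusted p = 0.403 with an estimated correlation. Of these, 1 was called higher and 4 lower, and 1 and 5 when adjusted over the list alone. OAS1 fell from 31.5 and 18.5 FPKM to 2.44 and 1.54 (log2 fold change −3.33, adjusted p = 0.025) and OAS2 fell by 2.05 on the log2 scale (adjusted p = 0.0497). These calls were lost without any one library, with adjusted p of 0.0546 to 0.335 for OAS1 and 0.0577 to 0.358 for OAS2. IFITM3 was listed at 0 in DMSO (1639 and 2171 in the resistant libraries). Alveolar and airway lineage genes were lower (10 genes, median −1.34, adjusted p = 0.0469), with an adjusted p = 0.75 with an estimated correlation. Of these, 1 was called lower, the same when adjusted over the list alone. That was NKX2-1, the lung lineage factor gene, with 121 and 123 FPKM against 30.3 and 21.9 (log2 fold change −2.23, adjusted p = 0.019). It was not called without any one library (0.0759 to 0.164). The list's call was lost without DMSO library A (0.229), resistant A (0.147) or resistant B (0.059).

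Other receptor tyrosine kinases and ligands were higher in HCC4006 (20 genes, median 0.51, adjusted p = 0.0458), with an adjusted p = 0.417 with an estimated correlation. Of these, 4 were called higher and 1 lower, the same when adjusted over the list alone. The list's call was lost without DMSO library B (0.106), resistant A (0.0833) or resistant B (0.0555), and over genes above 0 the list was not called (0.0912). Among its called members were PDGFRA (535 and 509.7 FPKM in the resistant libraries) and MST1R (48.1 and 40.5), both listed at 0 in DMSO. DDR1 fell by 1.78 on the log2 scale (adjusted p = 0.0467), a call lost without any one library (0.0714 to 0.412). MHC class I presentation genes were higher (12 genes, median 0.80, adjusted p = 6.94e-05), with an adjusted p = 0.431 with an estimated correlation. Of these, 5 were called higher, the same when adjusted over the list alone, but all 5 were listed at 0 in DMSO, PSMB9 (386 and 524) among them. Over genes above 0 this list was not called (0.167).

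None of the other lists was called by camera in HCC4006 over all measured genes. Over genes above 0, camera called 6 more: cell cycle genes (0.00482), ERK output and feedback genes (0.0181), the TGF-beta and BMP pathway (0.0353), cholesterol synthesis (0.0353) and FGF ligands and receptors (0.0447) higher, and EGFR family and ligands (0.0353) lower. With an estimated correlation, their adjusted p lay between 0.451 and 0.706. Fry called FGF ligands and receptors higher (adjusted p = 0.0127) and none of the others (0.137 to 0.793). For cell cycle and cholesterol synthesis genes the DMSO libraries stood apart by more than the change. All 29 cell cycle genes were lower in A than in B (median log2 A minus B −1.92, against a change of 0.786). So were 18 of 19 cholesterol synthesis genes (−1.42, against 0.581). Over all measured genes, FGF ligands and receptors (14 genes, adjusted p = 0.781) had 1 call, FGFR2, which was listed at 0 in the resistant libraries (17.5 and 5.78 FPKM in DMSO). It had 2 higher and 1 lower when adjusted over the list alone. The test pointed up and the median was 0.26, while the mean was −0.22. EGFR family and ligands (14 genes, 0.382) had 2 calls each way, and 3 higher and 4 lower when adjusted over the list alone. LRIG1 (8.86 and 15.1 FPKM in the resistant libraries) and NRG2 (5.43 and 5.81) were listed at 0 in DMSO, and ERBB2 and ERBB3 were lower. Camera placed this list lower and fry higher. ERK output and feedback genes (20 genes, 0.336) had SPRED3 higher (log2 fold change 1.93, adjusted p = 0.0337), a call lost without any one library (0.0786 to 0.183) and when adjusted over the list alone. Stem cell associated genes (12 genes, 0.854) had ITGA6 listed at 0 in DMSO (519 and 571), CD44 at 0 in the resistant libraries, and 2 calls each way when adjusted over the list alone. ALDH1A3 was lower (−4.53, adjusted p = 0.00839), not without resistant library A (0.267) or B (0.248). The list's test pointed up and its median was 0.17, while its mean was −0.65.

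Cell cycle genes (29 genes, adjusted p = 0.281) and neuroendocrine genes (8 genes, 0.593) had 1 call each in HCC4006, the same when adjusted over the list alone. These were BUB1B (104 and 269.8 FPKM in DMSO) and UCHL1 (35.9 and 16.3), listed at 0 in the resistant libraries. The neuroendocrine test pointed down, with a median of 0.03 and a mean of −0.56. BCL2 family and IAP genes (16 genes, 0.593) had BIRC3 higher (1.87, adjusted p = 0.0302) and BIK lower (−2.87, adjusted p = 0.0295), and 3 higher and 1 lower when adjusted over the list alone. Both calls were lost without any one library (0.0521 to 0.366 and 0.0779 to 0.316). Efflux, xenobiotic and NRF2 genes (21 genes, 0.444) and glycolysis genes (19 genes, 0.914) had 1 call each, the same when adjusted over the list alone. These were AKR1C3 (44.7 and 36.4) and PDK1 (220.3 and 45.5), listed at 0 in DMSO. The glycolysis test pointed down, with a median of 0.05 and a mean of 0.37. Immune cell markers (5 genes, 0.108) had CSF1R lower (−2.36, adjusted p = 0.012) and CD79A at 0 in the resistant libraries (6.61 and 15.9 in DMSO), and 1 higher and 3 lower when adjusted over the list alone. CSF1R was not called without DMSO A (0.055), resistant A (0.195) or resistant B (0.178).

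The TGF-beta and BMP pathway (21 genes, adjusted p = 0.239), cholesterol synthesis (19 genes, 0.336), unfolded protein and heat shock genes (16 genes, 0.141) and replication-dependent histone genes (12 genes, 0.914) had 0 calls by limma in HCC4006, and 0 when adjusted over the list alone. Of their members, 2, 0, 1 and 1 had an unadjusted p below 0.05, and fry called none of these lists. At an unadjusted p below 0.05, camera placed 11 of the 24 lists, camera with an estimated correlation 2 and fry 9, of which 10, 0 and 7 were called. Endothelial and fibroblast markers had fewer than 5 measured members and were not tested. PDGFRB, of the fibroblast list, rose from 2.57 and 0.764 FPKM to 21.9 and 26.2 (log2 fold change 3.64, adjusted p = 0.0385, and 0.412 and 0.444 without resistant library A and B). Single libraries moved list calls. Cell cycle genes were called lower without DMSO library A (0.0153) and higher without DMSO library B (6.68e-06). Efflux, xenobiotic and NRF2 genes were called higher without DMSO A (0.0162). Without DMSO B, cholesterol synthesis was called higher (0.00249) and unfolded protein and heat shock genes lower (0.00126).

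**Figure D2:**
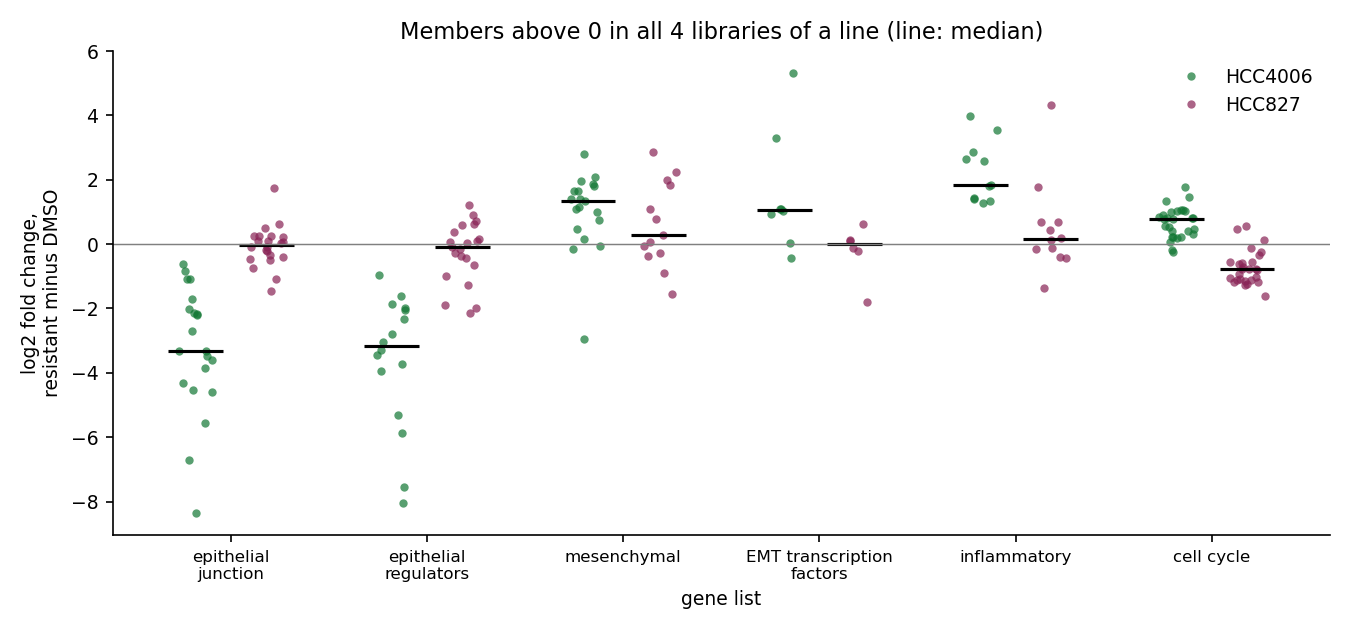
Log2 fold change, resistant minus DMSO, of members of 6 lists that lay above 0 in all 4 libraries of a line, 1 point per gene, with a bar at the median. Epithelial junction genes and regulators spread below 0 in HCC4006 and around 0 in HCC827.

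In resistant HCC827, SLC6A14, which encodes an amino acid transporter, the adhesion gene CNTN1 and the sulfotransferase gene SULT1C2 rose, while the drug efflux pump genes ABCG2 and ABCC2 and the organic anion transporter gene SLCO2A1 fell. Epithelial genes shared no direction. MET, a receptor kinase gene, VIM, FGF2, FGFR1 and ERBB2 were higher and EGFR was lower in both resistant libraries than in both DMSO libraries without passing the test. Calls in this line were lost when either DMSO library was left out, a fit whose spread comes from the resistant libraries alone. Lost power can cause this, so it does not show that the calls rest on a DMSO library.

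None of the 10 genes named in advance was called in HCC827. EGFR measured 5462 and 5246 FPKM in the DMSO libraries and 1639 and 424 in the resistant libraries, a log2 fold change of −2.68 (SE 0.70, adjusted p = 0.141), and MET 2567 and 2391 against 19878 and 6628 (2.21, SE 0.60, adjusted p = 0.154). EGFR passed the test without resistant library A (−3.66, adjusted p = 0.0273) and MET without resistant library B (3.00, adjusted p = 0.0495). In the fit over all 8 libraries EGFR (adjusted p = 0.0403), MET (0.038) and VIM (0.0346) passed. EGFR and VIM also passed with the replicate block by column letter, given below. VIM measured 155 and 341 FPKM against 800.4 and 1071 (2.01, SE 0.48, adjusted p = 0.113), FGF2 4.83 and 21.96 against 56.6 and 25.97 (1.83, SE 0.84, adjusted p = 0.356) and FGFR1 4.44 and 2.65 against 12.2 and 8.61 (1.45, SE 0.49, adjusted p = 0.226). The log2 fold changes of CDH1, ZEB1, ERBB2, ERBB3 and AXL were 0.26, −0.21, 1.16, 0.20 and −0.18, with adjusted p of 0.741, 0.829, 0.273, 0.877 and 0.882. Signs turned for CDH1 without resistant library A (−0.08), for ERBB3 without DMSO library B (−0.50) and for AXL without DMSO library B (0.23) or resistant library B (0.17).

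In HCC827, 1314 of 19324 genes were called, 991 higher and 323 lower, all at least 2-fold. Of these, 903 were listed at 0 in both DMSO libraries, 228 in both resistant libraries and 24 in 1 library. The other 159 lay above 0 in all 4, with 71 higher and 88 lower. Listed at 0 in DMSO were the row of GNB2L1 (25420.5 and 27128 FPKM in the resistant libraries), AP003035.1 (36930.1 and 9315) and the ferritin gene FTH1 (11668 and 10856). So were CAPZA2 (7718 and 6161), RPLP2 (4423 and 5944) and PBEF1 (6118 and 4058). Listed at 0 in the resistant libraries were PFN1 (7553 and 7748), PRDX1 (6555 and 8654) and the row of CHMP4A and NEDD8 (5169 and 5288). So were the tubulin gene TUBB (3061 and 3892), the row of RPS13 (2746 and 3737) and AC006368.1 (26706 and 2754). The limma count was 0 without DMSO library A and 0 without DMSO library B, where 2768 and 2574 genes had an unadjusted p below 0.05, and 1446 and 1520 without resistant library A and B. In the last 2, 1253 and 1363 were higher and 193 and 157 lower. Fitted over genes above 0 alone, 19 of 15917 were called, 10 higher and 9 lower.

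Among genes above 0 in HCC827, the largest rises were SLC6A14, CNTN1, SULT1C2, WFDC2, the row named hsa-mir-1184 and SMARCA1, with log2 fold changes of 7.57, 6.84, 6.56, 5.59, 5.58 and 5.48. The largest falls were the gene of the growth factor binding protein IGFBP2, ZNF704, ANKH, ABCG2, SLCO2A1 and CGREF1, with −6.76, −6.71, −5.55, −5.31, −5.15 and −4.90. SLC6A14 went from 4.74 and 2.57 to 400.4 and 1453 FPKM (adjusted p = 0.00538) and SULT1C2 from 1.07 and 1.64 to 186 and 159.6 (adjusted p = 0.000882). WFDC2 went from 31.4 and 14.1 to 851 and 1267 (adjusted p = 0.00409), and ABCG2 from 114 and 209 to 2.65 and 4.304 (adjusted p = 0.00411). In the fit over genes above 0, all 12 but CGREF1 (adjusted p = 0.0574) were called. Without DMSO library A or B, 0 of the 20 named called genes above 0 were called by limma, with adjusted p of SLC6A14, SULT1C2, WFDC2 and ABCG2 between 0.0609 and 0.217. Without resistant library A or B, SMARCA1, ANKH, SLCO2A1 and ABCC2 were called.

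By list, cell cycle genes were lower in resistant HCC827 (28 genes, 25 with negative changes, median −0.80, adjusted p = 0.00805), with an adjusted p = 0.886 with an estimated correlation. The resistant libraries stood apart for this list, with all 27 members above 0 lower in A (median log2 A minus B −1.49). Stem cell associated genes (9 genes, median −1.06, adjusted p = 0.0149) and replication-dependent histone genes (11 genes, median −0.84, adjusted p = 0.0379) were lower too, each with an adjusted p = 0.886 with an estimated correlation. Histone genes differed between the resistant libraries as well (9 of 10 lower in A, −0.54). After the trend on GC content and length was removed, that difference was −0.13, at percentile 12 of random lists. MHC class I presentation genes were higher (12 genes, median 0.78, adjusted p = 0.0149), with an adjusted p = 0.886 with an estimated correlation, and all 9 members above 0 in both DMSO libraries were higher in DMSO A than in B (1.16). Cell cycle genes had BUB1B, listed at 0 in the resistant libraries (247 and 223 FPKM in DMSO), as the 1 call, the same when adjusted over the list alone. The proliferation gene MKI67, chosen after its values were seen, measured 380 and 286 FPKM in DMSO and 92.5 and 214 in the resistant libraries. Stem cell associated genes had ABCG2 called lower, and 4 lower when adjusted over the list alone. Histone genes had HIST1H2BC called lower (log2 fold change −2.62, adjusted p = 0.0468), and 1 higher and 4 lower when adjusted over the list alone. HIST1H2BC was not called over genes above 0 alone (adjusted p = 0.116). MHC class I genes had 3 calls, the same when adjusted over the list alone, all listed at 0 in DMSO, PSMB8 (648 and 1786) and PSMB9 (708 and 1358.5) among them. Over genes above 0 the list was not called (0.151). The cell cycle call was lost without DMSO library B (0.0826) or resistant A (0.878), and the stem cell call without DMSO A (0.0631) or resistant B (0.0995). The histone call was lost without DMSO A (0.126) or resistant A (0.298), and the MHC class I call without DMSO B (0.167), resistant A (0.168) or resistant B (0.118).

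The remaining lists were not called in HCC827 over all measured genes. Over genes above 0, camera called interferon-stimulated genes lower (0.014), and cholesterol synthesis (0.014) and unfolded protein and heat shock genes (0.0348) higher. With an estimated correlation, their adjusted p lay between 0.884 and 0.905. The DMSO libraries stood apart for interferon-stimulated and cholesterol synthesis genes by more than the change. All 20 interferon-stimulated genes were higher in A than in B (median log2 A minus B 1.60, against a change of −0.78). Of 18 cholesterol synthesis genes, 17 were lower in A (−0.575, against 0.348). Over all measured genes, epithelial junction genes (23 genes, adjusted p = 0.417, median −0.08) had OCLN at 0 in the resistant libraries (280 and 307 FPKM) and 2 lower when adjusted over the list alone. Epithelial regulators and proteases (22 genes, 0.738, test down, median −0.03, mean 0.25) had OVOL2 at 0 in DMSO (805 and 1082) and GRHL1 lower (−1.89, adjusted p = 0.0453), the same when adjusted over the list alone. Mesenchymal genes (13 genes, 0.567) had FBN1 higher (2.87, adjusted p = 0.0345), and 2 higher and 1 lower when adjusted over the list alone. FGF ligands and receptors (12 genes, 0.597, camera down, fry up) had FGF13 at 0 in DMSO (182 and 131), FGFR3 at 0 in the resistant libraries (44.9 and 21.9), and 1 higher and 3 lower when adjusted over the list alone. FGF9 fell from 31.6 and 33.5 to 5.95 and 3.08 FPKM (−2.78, adjusted p = 0.0352). EGFR family and ligands (13 genes, 0.567) had EPGN at 0 in DMSO (271 and 377), the same when adjusted over the list alone. Other receptor tyrosine kinases and ligands (19 genes, 0.567, test up, median −0.01, mean 0.67) had PDGFRA (667 and 669.7) and ROR1 (23.7 and 14.1) at 0 in DMSO. PDGFB was lower (−4.01, adjusted p = 0.0246), and 5 were higher and 2 lower when adjusted over the list alone. The calls of GRHL1, FBN1, FGF9 and PDGFB were lost without any one library, with adjusted p from 0.0535 to 0.344 over the libraries and genes.

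ERK output and feedback genes (20 genes, adjusted p = 0.624) had EPHA4 lower in HCC827 (−3.43, adjusted p = 0.0104) and the TGF-beta and BMP pathway (20 genes, 0.515) had BAMBI lower (−2.37, adjusted p = 0.0315), the same when adjusted over the list alone. EPHA4 and BAMBI were lost without any one library (0.107 to 0.182 and 0.119 to 0.352). Interferon-stimulated genes (21 genes, 0.188, camera down, fry up) had IFITM1 at 0 in DMSO (573 and 864), the same when adjusted over the list alone. Efflux, xenobiotic and NRF2 genes (19 genes, 0.869, test down, median −0.00078, mean 0.33) had CYP1B1 at 0 in DMSO (296 and 185) and ABCC2 lower (−4.19, adjusted p = 0.0131), and 1 higher and 2 lower when adjusted over the list alone. ABCC2 was not called without DMSO A (0.24) or B (0.3). Cholesterol synthesis (19 genes, 0.0889) had LSS at 0 in DMSO (167 and 148), the same when adjusted over the list alone.

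Keratins (8 genes, adjusted p = 0.567), EMT transcription factors (9 genes, 0.567), alveolar and airway lineage genes (14 genes, 0.306), inflammatory cytokines and NF-kB targets (15 genes, 0.869), BCL2 family and IAP genes (16 genes, 0.597), glycolysis (19 genes, 0.622) and unfolded protein and heat shock genes (16 genes, 0.358) had 0 calls by limma in HCC827, and 0 when adjusted over the list alone. Of their members, 1, 1, 1, 3, 3, 1 and 5 had an unadjusted p below 0.05. Neuroendocrine, immune, endothelial and fibroblast lists had fewer than 5 measured members and were not tested. At an unadjusted p below 0.05, camera placed 5 of the 22 lists, camera with an estimated correlation 0 and fry 5, of which 4, 0 and 0 were called. Single libraries moved list calls here too. Inflammatory cytokines and NF-kB targets were called higher without DMSO library A (0.00428) and lower without DMSO B (0.0104), and interferon-stimulated genes lower without DMSO B (0.000336). Cholesterol synthesis was called higher without DMSO B (0.00543) or resistant A (0.0293), and glycolysis lower without resistant B (0.0227).

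Neighbouring genes moved together along parts of the HCC827 genome. EGFR lay in a stretch of chromosome 7 in which 22 of 23 genes were lower in the resistant libraries, and MET in a stretch in which 13 of 15 were higher. Most of the short arm of chromosome 17 was lower. SEC61G, LANCL2 and VOPP1, the neighbours of EGFR, were lower with it. These genes and regions were chosen after their values were seen.

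The row with SEC61G went from 44803 and 39392 FPKM to 13476 and 12678 (log2 fold change −1.68), LANCL2 from 2318 and 4093 to 621 and 728 (−2.20) and VOPP1 by −1.74. The 8 genes within 2 Mb of EGFR, EGFR left out, were all lower, with a median of −0.97 (−1.46 to −0.85 over the 4 pairs of a resistant and a DMSO library). This lay at percentile 1.69 of 8008 runs of as many genes, while in HCC4006 the median was −0.06 (percentile 41.8). Regions whose runs of 15 genes passed the permuted limits numbered 8 in HCC827. On chromosome 17, 55 of 57 genes between 62292 and 6943438 were lower (median −1.23), 58 of 64 between 7338761 and 26674035 (median −1.08) and 19 of 23 between 30819627 and 36904558 (median −0.86). On chromosome 7, the region of EGFR ran from 50657759 to 72425329 (median −1.06) and that of MET from 116312247 to 128550773 (median 0.84), and 17 of 19 genes between 536894 and 5273457 were higher (median 0.83). On chromosome 16, all 17 genes between 66543281 and 67237932 were higher (median 0.92), and on chromosome 1, 17 of 21 genes between 3696783 and 9884584 were lower (median −0.70). Genes near MET were few, 4 with a median of 0.53 (percentile 94.3), as CAPZA2 and others were listed at 0 in DMSO. In HCC4006, 3 genes near MET had a median of 0.635 (percentile 92.8, −0.596 to 1.63 over the 4 pairs of libraries). With so few genes and so wide a spread, these medians cannot tell whether higher values near MET were particular to HCC827. The stretch that holds MET passed the permuted limits in HCC827, and no region of chromosome 7 passed in HCC4006. After the trend on GC content and length was removed, 7 regions passed in HCC827. In HCC4006, 6 regions passed, and 4 after that trend was removed. Among the 6 were a lower region on chromosome 12 that holds ERBB3 (53905844 to 56615735, 24 of 27 genes lower, median −0.95) and a higher one on chromosome X (131157244 to 150067179, 25 of 28 genes higher, median 0.90). Genes are not independent replicates, and the regions are described, not tested between cultures.

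**Figure D3:**
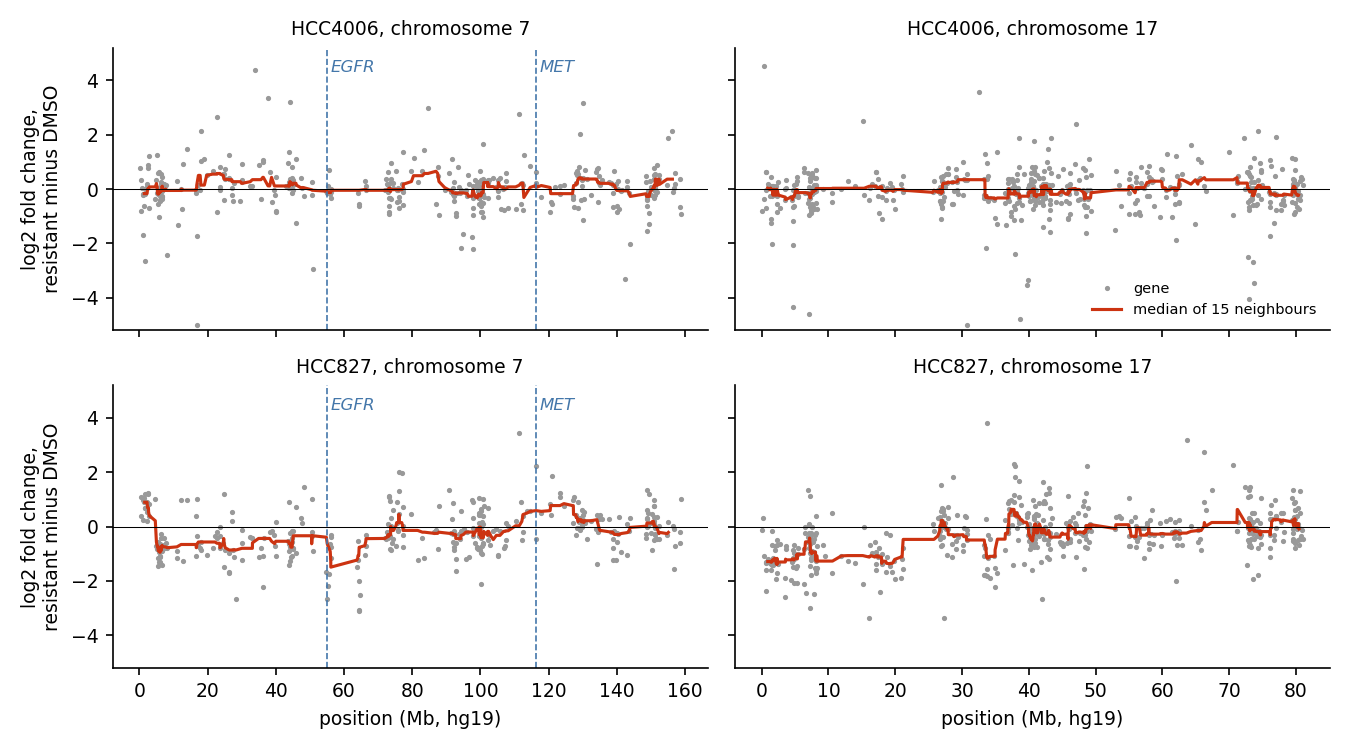
Log2 fold change, resistant minus DMSO, against position in Mb on hg19 for chromosomes 7 and 17, 1 point per gene above 0 in the line (points beyond ±5 drawn at the edge), with the median of 15 neighbours as a line. In HCC827 the line lies below 0 around EGFR and along the start of chromosome 17, and above 0 around MET; in HCC4006 it stays near 0 there.

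Epithelial genes differed between the lines, by single genes and by list. The lists lost their call with an estimated correlation (adjusted p = 0.275 for junction genes and for regulators), which need not come from correlated genes. The change in HCC827 lay above that in HCC4006 for CDH1, RAB25, AP1M2 and AGR2, as for WFDC2, the gene of a secreted protease inhibitor, and DHRS3, which encodes an enzyme of retinoid metabolism. It lay below for the transporter gene ABCG2, IL7R, the chaperone gene CLU, KIAA1644 and ZNF704, of which ZNF704 had a lower mean in the resistant than in the DMSO libraries of both lines. No difference between the lines passed the test for FGF2, FGFR1, EGFR, MET, AXL or VIM.

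The change differed between the lines for 2501 of 20685 genes, 1297 with the change in HCC827 above that in HCC4006 and 1204 below. Of these, 1726 had a group listed at 0 and 716 lay above 0 in all 8 libraries, and the fit over genes above 0 alone called 212 of 14642, 142 and 70. The count was 3857 without HCC4006 DMSO library B and 1666 without resistant HCC4006 library B. The difference was 8.61 for CDH1 (SE 0.48, adjusted p = 8.61e-05), −3.49 for ZEB1 (SE 0.53, adjusted p = 0.00821), 4.11 for ERBB3 (SE 0.83, adjusted p = 0.0262) and 2.30 for ERBB2 (SE 0.50, adjusted p = 0.0346, and 0.0735 over genes above 0). ZEB1 was not called without resistant HCC4006 library A (0.0522) or B (0.0543). ERBB3 was lost without HCC4006 DMSO A (0.0907), resistant A (0.139) or B (0.0784), and without HCC827 DMSO B (0.0718), resistant A (0.0879) or B (0.106). ERBB2 was lost without HCC4006 DMSO A (0.101), DMSO B (0.0715), resistant A (0.152) or B (0.149), and without resistant HCC827 A (0.0979) or B (0.0777). For EGFR, MET, FGFR1, FGF2, AXL and VIM the differences were −2.53, 2.00, −1.87, 0.57, −1.04 and 0.19, with adjusted p of 0.137, 0.141, 0.227, 0.769, 0.366 and 0.882. FGFR1 passed without HCC4006 DMSO B (−2.71, adjusted p = 0.0383), EGFR without resistant HCC827 A (−3.51, 0.0124), and MET without resistant HCC827 A (1.21, 0.0426) or B (2.79, 0.00371).

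WFDC2 differed most among genes above 0 (difference 11.82, SE 0.69, adjusted p = 0.000105), falling from 677 and 401 to 7.89 and 5.22 FPKM in HCC4006 and rising in HCC827. AGR2 (10.32), DHRS3 (9.42), RAB25 (8.96) and AP1M2 (8.78) followed, and RAB25 measured 535 and 320 FPKM in HCC827 DMSO and 654 and 934 in resistant HCC827. On the other side stood ABCG2 (−7.07), IL7R (−6.59), KIAA1644 (−6.27), CLU (−6.27) and ZNF704 (−6.18). ABCG2 measured 15.8 and 26.1 FPKM in HCC4006 DMSO and 75.2 and 64.9 in resistant HCC4006. CLU measured 29.8 and 71.6 against 895 and 1049.6 FPKM in HCC4006 and 26.5 and 65.2 against 6.83 and 16.98 in HCC827. The calls of IL7R (0.0649 and 0.0543), CLU (0.0615 and 0.068) and ZNF704 (0.0646 and 0.0536) were lost without resistant HCC4006 A and B, and that of AGR2 without resistant HCC4006 B (0.0576), HCC827 DMSO B (0.0516) or resistant HCC827 B (0.0573). WFDC2, DHRS3, RAB25, AP1M2, ABCG2, KIAA1644 and CDH1 were called without each library in turn.

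By list, the change in HCC827 lay above that in HCC4006 for epithelial junction genes (24 genes, median difference 2.58, adjusted p = 5e-07) and for epithelial regulators and proteases (23 genes, median 3.395, adjusted p = 2.22e-11). Each had an adjusted p = 0.275 with an estimated correlation, and fry gave adjusted p = 0.00516 and 0.00138. Junction genes had 17 members called above and 3 below, 18 and 3 when adjusted over the list alone, and regulators had 15 above, 16 when adjusted over the list alone. It lay below for EMT transcription factors (10 genes, all negative, adjusted p = 0.0321) and for cell cycle genes (29 genes, all negative, adjusted p = 0.0382). These had an adjusted p = 0.35 and an adjusted p = 0.765 with an estimated correlation, and 0.0125 and 0.455 by fry. Of the EMT factors 3 were called below, the same when adjusted over the list alone, and the list was not called without HCC827 DMSO B (0.108). Of the cell cycle genes 0 were called by limma, 0 when adjusted over the list alone, and 0 had an unadjusted p below 0.05. The cell cycle call was lost without HCC4006 DMSO A (0.723), resistant HCC4006 A (0.0528) or B (0.0932), HCC827 DMSO B (0.123) or resistant HCC827 A (0.44).

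Over genes above 0, the junction list was called between the lines with an estimated correlation as well (adjusted p = 0.0391), and the list of regulators was not (0.114). That fit did not call EMT transcription factors (0.0692). It called inflammatory cytokines and NF-kB targets (0.000646) and stem cell associated genes (0.00737) below and unfolded protein and heat shock genes (0.0222) above, lists not called over all measured genes. With an estimated correlation, these had adjusted p = 0.596, 0.224 and 0.649. Inflammatory genes were higher in library A in both DMSO groups, all 12 in HCC827 (median log2 A minus B 2.33) and 9 of 11 in HCC4006 (1.29). Unfolded protein and heat shock genes differed by 2.60 between the HCC4006 DMSO libraries, against a median difference of 1.64 between the lines.

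Most calls shared by the lines were of genes listed at 0. Of 17979 genes tested in both, 376 were called higher in both, where independent calls would share 44.1 (two-sided Fisher's exact test, p = 2.03e-275), but 366 of them were listed at 0 in both DMSO groups. Called lower in both were 26 (chance 7.81, two-sided Fisher's exact test, p = 8.83e-08), 17 of them at 0 in both resistant groups, and 73 went apart. Of the 402 that went the same way, 5 lay above 0 in all 8 libraries. Among 14552 genes in both fits over genes above 0, 65 and 6 genes were called lower in HCC4006 and HCC827, with 1 shared (chance 0.0268, two-sided Fisher's exact test, p = 0.0265), and 7 and 6 were called higher, with 0 shared (chance 0.00289, two-sided Fisher's exact test, p = 1). The 5 were IGFBP2 (log2 fold changes −3.80 in HCC4006 and −6.76 in HCC827), SPNS2 (−3.50 and −2.21) and GRHL1 (−2.32 and −1.89), which fell, and NPR3 (1.56 and 4.52) and RRAD (2.10 and 3.58), which rose. Called above 0 in opposite directions were WFDC2, DHRS3 and GALNT12 (−2.34 and 2.21), lower in HCC4006 and higher in HCC827, and DOCK11. These genes outside the naming rule were chosen after their values were seen. Across genes, which are not independent replicates, the changes correlated at a Pearson r of 0.285 and a Spearman rho of −0.0658, and at −0.105 and −0.169 over genes above 0.

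The 2 libraries of a group differed from each other by whole gene groups, most in HCC4006 DMSO, HCC827 DMSO and resistant HCC827. In HCC4006 DMSO, library A had lower cell cycle and cholesterol synthesis genes than library B and higher unfolded protein genes, such as HSPA5 and DDIT3, which cells raise under stress of the secretory pathway. In HCC827 DMSO, library A had higher interferon-stimulated, inflammatory and MHC class I genes. In resistant HCC827, library A had lower cell cycle and glycolysis genes. The resistant HCC4006 libraries were closest to each other, with smaller differences of gene lists.

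In HCC4006 DMSO, all 29 cell cycle genes were lower in A (median log2 A minus B −1.92, against −0.37 to 0.28 for the middle 95% of random lists), as were 18 of 19 cholesterol synthesis genes (−1.42). In turn, 14 of 16 unfolded protein and heat shock genes were higher (2.60), as were 13 of 18 efflux, xenobiotic and NRF2 genes (1.43) and 9 of 11 inflammatory genes (1.29). HSPA5 measured 23576 and 1146 FPKM and DDIT3 4773 and 80.1 in A and B. In HCC827 DMSO, all 20 interferon-stimulated genes (1.60, random lists −0.17 to 0.31), all 12 inflammatory genes (2.33) and all 9 MHC class I genes (1.16) were higher in A. There, 7 of 8 keratins were higher (1.08) and 17 of 18 cholesterol synthesis genes were lower (−0.57). In resistant HCC827, all 27 cell cycle genes (−1.49, random lists −0.49 to 0.15) and 18 of 19 glycolysis genes (−1.18) were lower in A. In resistant HCC4006, 19 of 22 mesenchymal genes (−0.28, random lists −0.16 to 0.14) and 17 of 28 cell cycle genes (−0.25) were lower in A, and 15 of 19 cholesterol synthesis genes were higher (0.23). Alveolar and airway lineage genes (6 of 7, −0.46), MHC class I genes (10 of 12, −0.25) and histone genes (9 of 11, −0.28) were lower there too. UBE2C, a mitosis gene, measured 285 and 2357 FPKM in resistant HCC827. HSPA5, DDIT3 and UBE2C were chosen after their values were seen. Over all genes the SD of A minus B was 1.09 in HCC4006 DMSO, 0.50 in resistant HCC4006, 0.85 in HCC827 DMSO and 0.92 in resistant HCC827.

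**Figure D4:**
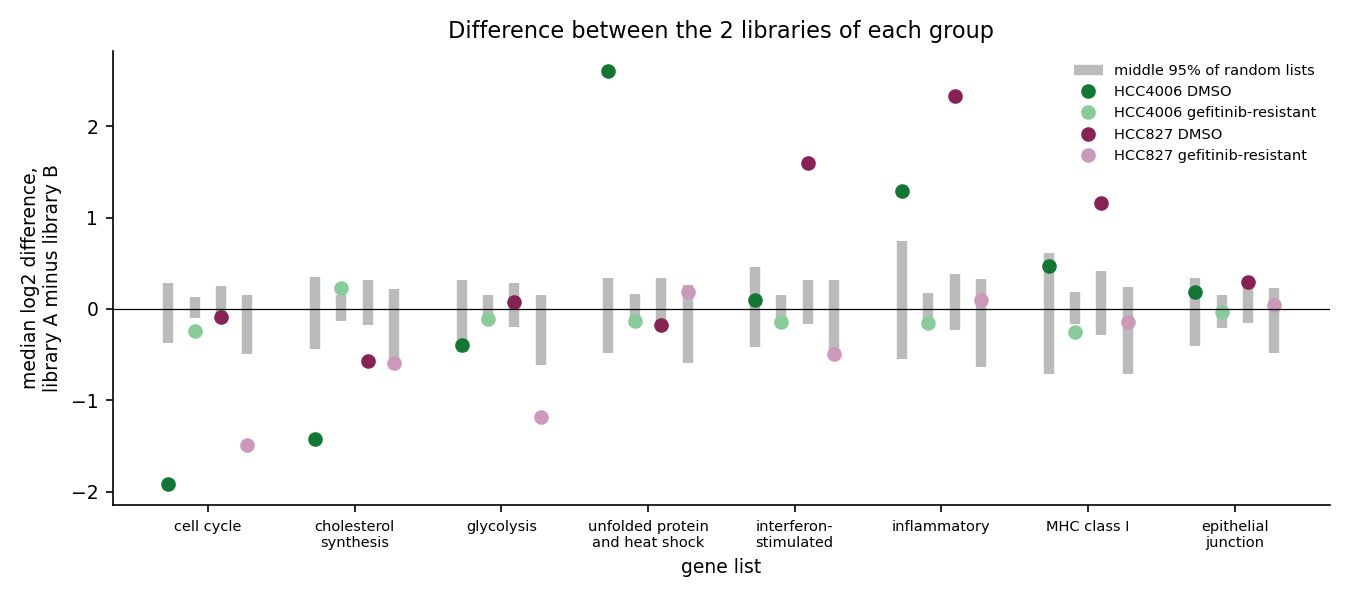
Median log2 difference, library A minus library B, of 8 gene lists in the 4 groups, as points, with grey bars for the middle 95% of random lists matched on mean FPKM. Cell cycle genes in HCC4006 DMSO (−1.92) and resistant HCC827 (−1.49) and interferon-stimulated genes in HCC827 DMSO (1.60) lie far outside their bars.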

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

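The tests of the zeros, of library scaling and of the region around EGFR were chosen after their results were seen, while those of GC content and transcript length were set before their outcome.

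The test of the difference between the lines singled out the following results. The change differed between HCC827 and HCC4006 for 2501 genes. By list it differed for epithelial junction genes (adjusted p = 5.004e-07), epithelial regulators and proteases (adjusted p = 2.22e-11), EMT transcription factors (adjusted p = 0.0321) and cell cycle genes (adjusted p = 0.0382). With an estimated correlation these had adjusted p = 0.275, 0.275, 0.35 and 0.765, and 0 cell cycle genes had an unadjusted p below 0.05 by limma, with 0 called. Among genes named in advance, the difference on the log2 scale, HCC827 minus HCC4006, was 8.61 for CDH1, 4.11 for ERBB3, 2.30 for ERBB2 and −3.49 for ZEB1. Among other genes above 0 it was 11.82 for WFDC2, 10.32 for AGR2, 9.42 for DHRS3, 8.96 for RAB25 and 8.78 for AP1M2, and −7.07 for ABCG2, −6.59 for IL7R, −6.27 for KIAA1644, −6.27 for CLU and −6.18 for ZNF704.

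The same test singled out 10 genes with groups listed at 0. PFN1 (adjusted p = 1.26e-06), PRDX1 (2.5e-06), PYGL (6.06e-06), TMEM50A (7.19e-06) and the row of RP11-163O17.1 and SEC31A (8.53e-06) were listed at 0 in HCC4006 DMSO and in resistant HCC827. CTC-329H14.1 (8.53e-06), STK10 (1.12e-05) and DENND3 (1.24e-05) were listed at 0 in resistant HCC4006 and in HCC827 DMSO. The row of GNB2L1 (9.85e-06) was at 0 in HCC827 DMSO alone, and AC091047.2 (0.000516) in resistant HCC4006 alone.

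Many calls came from groups listed at 0, most of them in DMSO. Genes switched off in a culture would leave ribosomal protein genes above 0, but 10 of these were at 0 in both libraries of a group while over 1000 FPKM in a library of another, which argues against this as the whole cause. Estimates that failed for whole loci would put neighbours on a locus at 0 together, and in each group the other gene was at 0 too in at least 81.5% of pairs of high genes on a locus with 1 at 0. The zeros are consistent with failed estimates, so a call that rests on a group at 0 may carry no biology. Single genes among them could still be silent, which the tables cannot settle.

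In HCC4006 DMSO, HCC827 DMSO and resistant HCC827, the median of some gene lists differed by over 1 on the log2 scale between the 2 libraries, and less in resistant HCC4006. A library scaled differently would shift all genes, but the median of all genes differed by at most 0.11 between A and B in these 3 groups. After the trend on GC content and length was removed, the median of cell cycle genes stayed at −1.99 in HCC4006 DMSO and −1.41 in resistant HCC827, and that of interferon-stimulated genes at 1.79 in HCC827 DMSO, which argues against this trend as the cause. The design names no difference between the libraries of a group, so no biological explanation was tested. Differences in growth, culture or RNA handling may remain behind these lists.

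EGFR and its neighbours were lower in resistant HCC827. The other genes within 2 Mb had a median log2 fold change of −0.966, in the lowest 2.5% of such runs, which describes the pattern and cannot bear out its cause. Library scaling would lower all genes alike, but the median of the genes used for the runs, with a mean of at least 20 FPKM, was −0.14, and after the trend on GC content and length the region stayed at −1.12. As a hypothesis that no test here decides, the region could be present in fewer copies in the resistant culture. Copy number was not analysed here, and regulation of the region stays open as well.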

How the results depend on the processing

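The fits over genes above 0, with a pseudocount of 10, with a mean FPKM of at least 20, and over genes above 0 with the replicate block were chosen after seeing the data, and the others were planned. Where a result changed, the cause was not tested unless one is given.

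The ranges in this paragraph leave out the fit over genes above 0 with the replicate block, whose counts stand with the block. The 1860 calls in HCC4006 became 88 over genes above 0 and 1201 at a mean FPKM of at least 20, and lay between 1400 and 2247 under the other settings. The 1314 calls in HCC827 became 19 over genes above 0 and lay between 930 and 1808 otherwise. The 2501 differences between the lines became 212 over genes above 0 and 1649 at a mean FPKM of at least 20, and lay between 1687 and 2558 otherwise. The 402 shared calls became 1 over genes above 0 and lay between 318 and 479 otherwise. Leaving out genes at 0 removes their calls by construction. It also left far fewer calls among the genes that remained, 88 instead of 499 in HCC4006 and 19 instead of 159 in HCC827. At an unadjusted p below 0.05 by limma, these genes numbered 2782 in the main fit and 2704 without rows at 0 in HCC4006. In HCC827 they numbered 1920 and 2033. These counts hardly moved, while the adjustment runs over all rows of a fit. Calls of genes above 0 in the main fit thus depend in part on the rows at 0.

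The 10 lists called in HCC4006 became 0 with an estimated correlation and 7 by fry. Fry did not call inflammatory (adjusted p = 0.0571), interferon-stimulated (0.65) or alveolar and airway lineage genes (0.262) there. The 4 lists called in HCC827 became 2 with no filter, 0 with an estimated correlation and 0 by fry. Quantile normalization called 2 lists higher and 2 lower in HCC827, where the reported split was 1 and 3. It lowered the median log2 fold change of all genes to −0.191 in HCC4006 and −0.243 in HCC827, from −0.00722 and −0.0444.

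With each library left out, the lone library of a group was assumed to vary like the other group. These fits have fewer residual degrees of freedom, so lost calls can come from lost power. The lowest and highest counts of calls were 1394 and 3565 in HCC4006, 0 and 1520 in HCC827, and 1666 and 3857 for the difference. Lists called numbered 7 to 12 in HCC4006 and 2 to 5 in HCC827.

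Beyond left-out libraries, some lists turned in direction, none of them called. In HCC4006 these were glycolysis (adjusted p = 0.307) and histone genes (0.839) with quantile normalization. In HCC827 they were inflammatory genes with no filter (0.967), epithelial regulators (0.903) and efflux genes (0.955) with quantile normalization, and FGF genes over genes above 0 (0.745) and at a mean FPKM of at least 20 (0.279). Between the lines, the difference turned to −0.027 for VIM with quantile normalization and to −0.0182 for FGF2 with a pseudocount of 10.

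Results whose direction turned without a single library had these lowest and highest values. Log2 fold changes were −0.50 to 0.20 for EGFR in HCC4006, and in HCC827 −0.50 to 0.90 for ERBB3, −0.59 to 0.23 for AXL and −0.08 to 0.59 for CDH1. Differences between the lines were −0.38 to 0.76 for VIM and −0.47 to 1.60 for FGF2. Adjusted p of lists in HCC4006 were 6.68e-06 to 0.656 for cell cycle, 0.00249 to 0.843 for cholesterol synthesis, 0.00126 to 0.916 for unfolded protein and heat shock, 0.41 to 0.748 for histone, 0.627 to 0.856 for stem cell, 0.0162 to 0.791 for efflux, 0.206 to 0.843 for glycolysis, 0.711 to 0.843 for FGF and 0.297 to 0.843 for neuroendocrine genes. In HCC827 they were 0.417 to 0.91 for epithelial regulators, 0.0826 to 0.953 for keratins, 0.000336 to 0.809 for interferon-stimulated, 0.658 to 0.978 for efflux, 0.00428 to 0.953 for inflammatory, 0.466 to 0.978 for BCL2 family and 0.0227 to 0.678 for glycolysis genes.

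The libraries share only a letter, and a replicate block by column letter gave 1400 calls in HCC4006, 1485 in HCC827, 1687 differences and 396 shared calls. It called FGFR1 in HCC4006 (adjusted p = 0.0318) and EGFR (0.0444) and VIM (0.0323) in HCC827, and not ERBB2 in HCC4006 (0.182) or the difference of ERBB3 (0.0814). Glycolysis in HCC4006 turned in direction (adjusted p = 0.97). Over genes above 0 with the replicate block, counts were 311, 341, 173 and 10, and FGF genes (0.848) and glycolysis (0.991) turned in HCC827. That fit called FGFR1 in HCC4006 (0.0103), and EGFR (0.0234) and VIM (0.0263) in HCC827. It did not call ERBB2 in HCC4006 (0.242), nor the differences of ERBB2 (0.0721), ERBB3 (0.0537) and ZEB1 (0.0547). Differences between A and B correlated across genes at −0.0806 between the groups of HCC4006 and 0.21 between those of HCC827, but also at 0.334 between the DMSO groups of the 2 lines.

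Of the comparisons of single genes with other settings, left-out libraries aside, 730 kept direction and side of the threshold in HCC4006, 68 lost the call and 6 gained it. In HCC827 these were 628, 21 and 7, and for the difference 332 and 5, with 0 gained. ERBB2 in HCC4006 lost its call under several settings, a pseudocount of 1 (adjusted p = 0.051) among them. List tests were not run without the trend or over all 8 libraries. Depth is unknown, so what a low value or a 0 can exclude is not given.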

Other observations

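In HCC4006, genes at the start of chromosome 11 (207510 to 842545) were lower together. All 18, among them PKP3, HRAS and CD151, had negative fold changes, with a median of −0.954, and of −0.5 after the trend on GC content and length was removed. A region of chromosome 19 (45504694 to 47261832), with RELB, VASP and FOXA3, had 25 of 26 genes lower (median −0.943), and one of chromosome 12 (57031962 to 60175407), with CDK4 and STAT6, 19 of 21 (median −0.761). A region of chromosome 4 (68337520 to 77069668) held the chemokine genes IL8, CXCL1, CXCL2 and CXCL5, with 14 of 21 genes higher (median 0.243). These regions and genes were chosen after their values were seen, and the regions were not tested between cultures.

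RRAD, a gene of a small GTPase that rose in both lines, lay in the higher region of chromosome 16 in HCC827. It measured 88.7 and 85.1 FPKM in HCC4006 DMSO and 373 and 376 in resistant HCC4006, and 15.996 and 19.4 in HCC827 DMSO and 364 and 129 in resistant HCC827. FOSL1, an AP-1 gene chosen after its values were seen, measured 105 and 1423 FPKM in HCC4006 DMSO and 2031 and 2398 in resistant HCC4006 (adjusted p = 0.392). Among rows that reached 50 FPKM in some library, those at 0 in both libraries of a group lay on wider loci than the others, with median widths of 141557 against 35984 bases in HCC4006 DMSO, 65895 against 39706 in resistant HCC4006, 120953 against 35987 in HCC827 DMSO and 96084 against 38992 in resistant HCC827.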
